A study of Homo sapiens with 12 samples.

How the data were processed

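Gene expression was measured by directional RNA-seq of total RNA in 12 libraries of the GM12878 cell line, 3 in each of 4 groups, all labelled with the same batch. FPKM values were deposited by the authors in a single table. They are reads scaled by gene length and by an effective library size, listed with Ensembl gene identifiers, coordinates, gene lengths and biotypes on build GRCh38 per the labels. The gene length column, deposited with the values, gives the length of each gene model in bases. Aligner, counter and normalization were not given in the sources used here. FPKM times gene length fell in every library on whole multiples of 1 step. Dividing by that step gave whole reads for 100% of values above 0 (tolerance 0.01 read) and between 14403225 and 16291132 reads per library. The library size implied by the values was 0.975 to 1.029 times the reads recovered, and median-of-ratios factors of the FPKM over 18198 genes were 1.0027 to 1.0096.

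Of 64147 genes listed, the 11951 with a mean of at least 1 FPKM over the 12 libraries were tested, of which 9396 were protein-coding. Tested genes included 442 unnamed loci, 321 genes on sequences outside the main chromosomes and 279 genes whose FPKM (offset 0.1, at least 50 reads) differed over 4-fold between replicates of a group. In the table, a single line was not used here. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 (R 4.3.3) with a variance trend, in 1 fit over all 12 libraries with a term per group, and p-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons at 0.05. The comparisons were pH 6.8 against pH 7.4, each additive against pH 6.8, NMN against the PARP1 inhibitor, and each additive against pH 7.4. In principal component analysis the log2 values were centred by gene. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so differences rest on the spread pooled over genes and groups.

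In data simulated from these libraries, with 50 genes changed at each fold and 11751 unchanged, the fit recovered 38%, 80%, 90% and 94% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold with the right sign for pH 6.8 against pH 7.4, with 8 unchanged genes called. For NMN against pH 6.8 it recovered 40%, 80%, 70% and 90%, with 7 called, and for the PARP1 inhibitor against pH 6.8 46%, 66%, 82% and 92%, with 8 called.

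A set of 46 gene lists was fixed before the data were examined, as were the comparisons, the test, the filter and most alternatives. Of these lists 44 had at least 3 measured members and were tested; monocyte and macrophage markers and erythroid markers had too few. Lists were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from each list. The fry test, which asks whether a list moves on balance 1 way and does not compare it with other genes, was run beside it. Of the 20, 11, 14 and 19 lists that camera called in acid culture, with NMN, with the PARP1 inhibitor and between the additives, fry also called 20, 10, 13 and 19. Among all 44 lists fry called 31, 16, 24 and 31, so part of this overlap comes from how many lists it calls. The median, the mean and the camera direction of each called list had the same sign. Overlaps between comparisons were set beside the number that independent lists would share. Covariances between changes were set beside 1000 simulations of unchanged groups that shared the pH 6.8 libraries. For the share of acid changes kept with an additive, all 12 libraries were drawn 100 times around the group means, with the additive groups placed at the pH 7.4 means; this was added after the data were seen.

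Genes were named by a rule fixed beforehand. It took, per comparison, the 8 largest rises and 8 largest falls among protein-coding genes with an adjusted p under 0.05 and no overlap between groups. It added up to 4 members with the smallest p of each list described, and NAMPT, NMNAT1, NNMT, CD38, SIRT1, PARP1, TXNIP, LDHA, HK2, CDKN1A and MDM2. Which of these genes are printed, and which are plotted per library, was chosen after the values were seen. Some genes that the rule picked are not reported here. Alternatives were an offset of 0.1 in place of 1, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, only the libraries compared, a term for the replicate number, no variance trend, and leaving out each library. Voom on the recovered reads, a robust variance prior, and leaving out genes unstable between replicates were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and version 1.17.8 of data.table.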

Results

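RNA was measured in GM12878, an established human lymphoblastoid cell line made by transforming B cells with Epstein-Barr virus. Cultures were kept in bioreactors at a controlled pH for 72 h, and the design asks how mildly acid culture changes gene expression and whether changing the supply or use of NAD+ alters that state. The 12 RNA-seq libraries formed 4 groups of 3: pH 7.4, pH 6.8, pH 6.8 with 0.5 mM nicotinamide mononucleotide (NMN, a precursor of NAD+), and pH 6.8 with 5 µM rucaparib, an inhibitor of the NAD+-consuming enzyme PARP1. Per the series' design text the additives were also run at pH 7.4, but none of the 12 libraries is of those conditions. An effect of an additive in acid culture therefore cannot be told apart from an effect it has at any pH. The values imply between 14403225 and 16291132 reads assigned to genes per library. Of 64147 genes listed, the 11951 with a mean of at least 1 FPKM were tested. Changes are given on the log2 scale of FPKM + 1, which understates changes of weakly expressed genes, and SE is the standard error of a log2 change.

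Correlations over genes were 0.972 to 0.976 between libraries of a group and 0.952 to 0.973 between libraries of different groups, so the ranges met at their ends. The first principal component (21.6% of the variance) set the pH 7.4 libraries (scores of 20.55 to 24.24) apart from those at pH 6.8 without additive (-5.21 to -0.80) and those with the PARP1 inhibitor (-18.45 to -16.67). The second component (13.2%) separated the pH 6.8 libraries (13.53 to 17.24) from the NMN libraries (4.92 to 5.74). Nothing in the labels says whether the 3 replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries.

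Lowering the culture pH from 7.4 to 6.8 raised 15 of 18 measured NF-kB targets and cytokines (adjusted p = 1.49e-10) and lowered 16 of 20 plasma cell differentiation genes (adjusted p = 3.23e-12). CCL22, a chemokine that attracts cells bearing CCR4 (ENSG00000102962; chromosome 16, 57358783 to 57366189, GRCh38), rose 3.28-fold, from 59.7 ± 1.51 to 195.6 ± 9.83 FPKM (SD, n = 3). The immediate early transcription factor EGR1 (ENSG00000120738; chromosome 5, 138465479 to 138469303) rose 3.93-fold, from 3.88 ± 0.269 to 15.2 ± 1.11 FPKM. JCHAIN, which joins the units of secreted IgM and IgA (ENSG00000132465; chromosome 4, 70655541 to 70681817), fell 2.73-fold, from 284.9 ± 13.8 to 104.5 ± 1.20 FPKM. In the limma fit 3737 genes changed, of which 2038 rose and 1699 fell. Most changes were small, with 41 rises and 48 falls of over 1 log2 unit.

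Among the largest rises were the chemokines CCL20 (log2 change 1.64, SE 0.102, adjusted p = 2.66e-06) and XCL2 (1.68, SE 0.136, adjusted p = 1.42e-05), the second of which has a near-identical paralog that could share its reads. CR2, the complement receptor that Epstein-Barr virus uses to enter B cells, rose by 1.54 (SE 0.057, adjusted p = 1.42e-07). CSF2RB, the receptor chain shared by interleukin 3, interleukin 5 and GM-CSF, rose by 1.29. NAPRT, which makes NAD+ from nicotinic acid, rose by 1.65, but its FPKM differed over 4-fold between replicates. Its call was lost without pH 6.8 replicate 2 (adjusted p = 0.0823) or 3 (0.0807) or pH 7.4 replicate 2 (0.0988) or 3 (0.0676), or without a filter on low values (0.0861). Among protein-coding genes, the largest fall besides JCHAIN was in TENT5C, a poly(A) polymerase that stabilizes immunoglobulin mRNAs (-1.76, SE 0.11, adjusted p = 2.71e-06). MACROD2, which removes ADP-ribose from proteins, came next (-1.43, SE 0.07). They were followed by RCBTB2 (-1.33), the chemokine-like GPR15LG (-1.27), BHLHA15, a transcription factor of secretory cells (-1.26), and the linker histone H1-2 (-1.24). MACROD2, RCBTB2, NMNAT1 and MDM2 overlap other gene models on the same strand, so their read assignment is less certain.

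The falls included many genes of the plasma cell, unfolded protein response and ATF4 lists. Of 20 measured genes of the plasma cell differentiation list, 16 fell and the other 4 did not pass. Of the same genes 17 fell adjusted over the list alone, with a median of -0.60 (camera adjusted p = 3.23e-12). They included IGKC (-1.17), whose reads can be shared with other immunoglobulin genes, TNFRSF17, the receptor BCMA (-0.82), and PRDM1, the transcription factor BLIMP-1 (-1.21). Of 20 measured genes of the endoplasmic reticulum unfolded protein response, 18 fell (19 adjusted over the list alone, median -0.31, adjusted p = 1.91e-12), among them XBP1 (-0.72), HSPA5 (-0.46), PDIA4 (-0.50) and SEL1L (-0.39). Of 25 measured genes of the ATF4 and amino acid response list, 19 fell (21 adjusted over the list alone, median -0.35, adjusted p = 8.8e-12), with the serine synthesis enzyme PSAT1 at -1.05 and ATF4 itself at -0.48. The serine and one-carbon list, which shares PSAT1, had a median of -0.15 with 8 falls and 1 rise among 16 (9 and 2 adjusted over the list alone, adjusted p = 0.00141), a call lost with adjusted p = 0.101 with an estimated correlation.

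Replication-dependent histone genes, whose mRNAs lack the poly(A) tail of others, fell by the largest median, -0.77, with 16 of 22 measured members falling (17 adjusted over the list alone, adjusted p = 4.7e-09). Among them H4C8 changed by -0.81, H2BC9 by -0.89 and H2AC6 by -0.82. Genes that drive DNA replication and G1/S moved far less, with a median of -0.09, 14 falls and 2 rises among 41 (15 and 2 adjusted over the list alone, adjusted p = 0.0033, and adjusted p = 0.243 with an estimated correlation). The nucleotide reductase RRM2 changed by -0.31 and CDC6 by -0.35. Of 33 p53 targets, 19 fell (20 fell and 2 rose adjusted over the list alone, median -0.21, adjusted p = 1.65e-05), including TP53INP1 (-0.63), MDM2 (-0.40) and the cell cycle inhibitor CDKN1A (-0.34). Cholesterol synthesis genes fell as well, in 14 of 22 members and also in 14 adjusted over the list alone (median -0.20, adjusted p = 3.76e-06), with HMGCS1 at -0.45 and INSIG1 at -0.38. In the fatty acid synthesis list 5 of 12 fell and 1 rose (5 and 2 adjusted over the list alone), led by the desaturase SCD (-0.61) and the transcription factor SREBF1 (-0.46). Its median was -0.06 (adjusted p = 0.0191, and adjusted p = 0.239 with an estimated correlation).

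NF-kB targets and cytokines rose in 15 of 18 measured members (16 adjusted over the list alone, median 0.44, adjusted p = 1.49e-10), among them TNFAIP2 (1.12), the survival factor BCL2A1 (0.55) and the receptor CD40 (0.46). Of 28 interferon-stimulated genes, 23 rose and 2 fell, the same counts adjusted over the list alone (median 0.30, adjusted p = 1.52e-09), and the antiviral genes OAS3, MX2 and IFIT5 rose by 0.71, 0.50 and 0.44. Fatty acid oxidation genes rose in 9 of 17 (10 adjusted over the list alone, median 0.14, adjusted p = 0.0006), with the carnitine transferase CPT1A at 0.50 and ACADVL at 0.62. These 3 lists, and the 6 falling lists of plasma cell, unfolded protein response, ATF4, histone, p53 and cholesterol genes, kept an adjusted p under 0.05 with an estimated correlation. Over the alternatives, that correlation included, their highest adjusted p ran from 0.00159 (plasma cell genes) to 0.039 (fatty acid oxidation).

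Other rising lists passed only with the preset correlation. The 13 protein-coding genes of the mitochondrial genome had a median of 0.34, with 11 rising (12 adjusted over the list alone, adjusted p = 9.67e-07, and adjusted p = 0.183 with an estimated correlation). The cytochrome b gene MT-CYB rose by 0.48. All genes of the mitochondrial chromosome together took 6.02 ± 0.277% of reads at pH 7.4 and 7.35 ± 0.114% at pH 6.8 (SD, n = 3). After quantile normalization the median of the 13 was 0.11 (adjusted p = 0.124, from 1.25e-09 to 0.183 over the alternatives). B cell identity genes (12 rose and 2 fell of 23; 15 and 4 adjusted over the list alone, median 0.17, adjusted p = 0.00274) included CD22 (0.40) and IRF8 (0.34), with adjusted p = 0.106 with an estimated correlation. MHC class II genes (5 rose of 8, also adjusted over the list alone, adjusted p = 0.00511) included HLA-DRB1 (0.55), a gene of the MHC region, where alternate copies can share reads, with adjusted p = 0.195 with an estimated correlation. Glycolysis genes (9 rose and 2 fell of 20; 10 and 2 adjusted over the list alone, adjusted p = 0.00274) included ENO2 (0.81) and HK1 (0.35), with adjusted p = 0.384 with an estimated correlation. The tricarboxylic acid cycle list (8 rose and 1 fell of 18; 9 and 1 adjusted over the list alone, adjusted p = 0.00546) included IDH2 (0.42), with adjusted p = 0.14 with an estimated correlation. Heat shock genes (4 rose of 14; 5 adjusted over the list alone, adjusted p = 0.0042) included HSPB1 (0.84), with adjusted p = 0.109 with an estimated correlation. Immediate early genes (7 rose and 3 fell of 16; 8 and 3 adjusted over the list alone, adjusted p = 0.019) included EGR3 (0.98) and DUSP2 (1.04), with adjusted p = 0.23 with an estimated correlation. T and NK cell markers (2 rose of 5; 3 adjusted over the list alone, adjusted p = 0.0432) included TRAC (0.37) and NKG7 (0.72), with adjusted p = 0.14 with an estimated correlation. Of the 17 T and NK cell markers fixed, 5 reached 1 FPKM, TRAC being highest at 92.7 FPKM over all libraries.

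The remaining 24 lists did not pass (adjusted p from 0.0835 to 0.978), including those closest to acid sensing and NAD+. Among 11 measured genes of pH regulation the bicarbonate transporter SLC4A7 rose (0.42; list adjusted p = 0.751). Among 5 proton-sensing receptors and channels GPR65 rose (0.34; list adjusted p = 0.95). In the NAD metabolism list 3 of 19 rose and 4 fell (adjusted p = 0.165): NMNAT1, a nuclear NAD+ synthase, fell by 0.22, while NAMPT, the enzyme that recycles nicotinamide, was at -0.06 (adjusted p = 0.193) and the NAD+ hydrolase CD38 at -0.14 (adjusted p = 0.202). PARP1 was at 0.08 (adjusted p = 0.0677, passing without NMN replicate 3, 0.0249, and after quantile normalization, 0.0302) within a PARP family list of which 7 of 18 rose and 2 fell (adjusted p = 0.191). SIRT1 was at -0.03 (adjusted p = 0.764; sirtuin list adjusted p = 0.796), hexokinase HK2 at 0.07 (adjusted p = 0.0803), and TXNIP rose by 0.21 (adjusted p = 0.00366). LDHA and NNMT were listed near 0 in every library and were not tested. Nuclear-encoded complex I genes (7 of 31 rose; adjusted p = 0.0835), complexes II to V (5 of 37 rose and 1 fell; adjusted p = 0.191) and hypoxia-inducible factor targets (3 of 15 rose and 3 fell; adjusted p = 0.506) did not pass either. The same held for mitochondrial ribosomes (adjusted p = 0.265), mitochondrial biogenesis and mitophagy (0.351), the mitochondrial unfolded protein response (0.407), autophagy (0.407), lysosomes (0.319), the vacuolar ATPase (0.839), NRF2 targets (0.505) and MHC class I (0.848). Apoptosis (adjusted p = 0.848), homologous recombination (0.135), G2/M (0.265), MYC and ribosome biogenesis (0.148), cytosolic ribosomal proteins (0.978), the MondoA and TXNIP family (0.796), senescence-associated secretion (0.191) and the 3 measured fibroblast and epithelial markers (0.407) completed the set.

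At an unadjusted p under 0.05, 4991 genes differed between pH 6.8 and pH 7.4, and 46.25% of tested genes had groups that did not overlap, against 10% given by chance for 3 libraries against 3. The call of NMNAT1 was lost without pH 6.8 replicate 3 (adjusted p = 0.0709) or pH 7.4 replicate 1 (0.0725), without a filter on low values (0.051), and with only the 6 libraries compared (0.0565). That of the T and NK cell markers was lost without pH 6.8 replicate 1 (0.0735), pH 7.4 replicate 2 (0.0521) or PARP1 inhibitor replicate 2 (0.0515) or 3 (0.0611). Complex I genes passed without pH 6.8 replicate 1 (0.0496) or pH 7.4 replicate 1 (0.0429), and complexes II to V without pH 6.8 replicate 1 (0.0417). Without a filter on low values 5 lists passed that had not: complex I (0.00289), complexes II to V (0.0155), the PARP family (0.0155), mitochondrial ribosomes (0.0279) and G2/M (0.0399). The T and NK cell markers also lost their call with only the 6 libraries compared (0.0642) and with voom (0.0698).

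**Figure D1:**
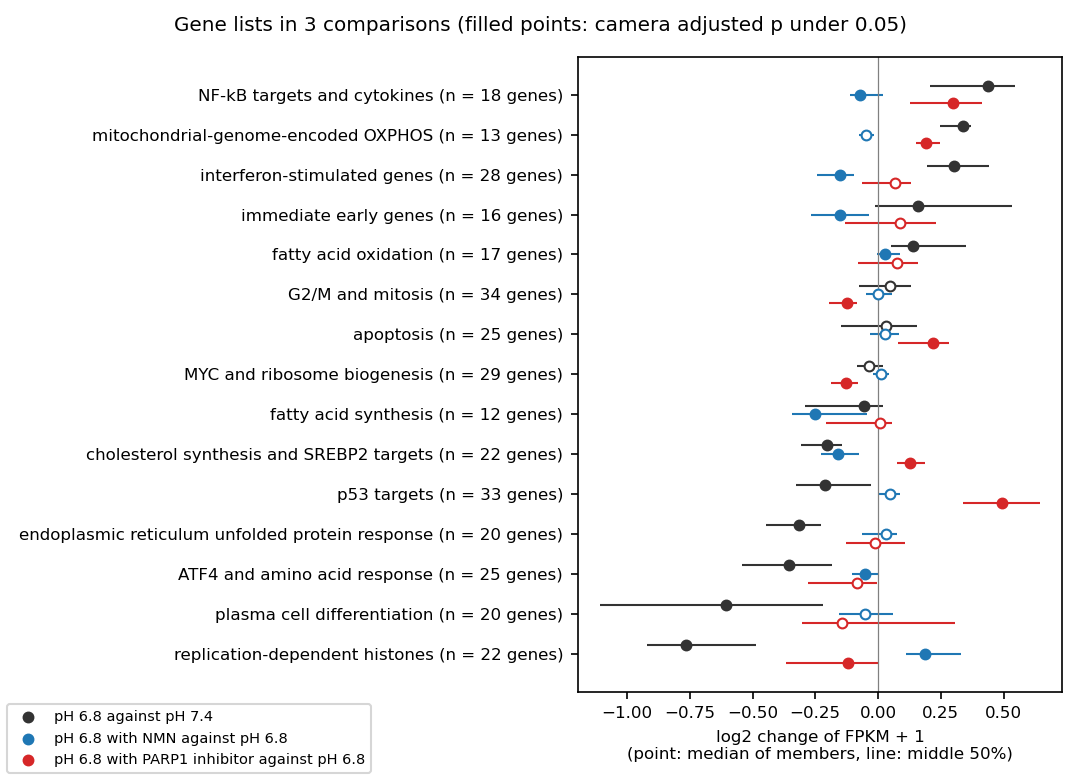
Median log2 change of FPKM + 1 (x axis) of gene lists (y axis) in acid culture and with each additive; points are medians of the measured members, lines span the middle 50% of members, and filled points had a camera adjusted p under 0.05. In acid culture the plasma cell list lay at -0.60 and NF-kB targets at 0.44, and with the PARP1 inhibitor p53 targets lay at 0.50.

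Adding NMN to the acid culture lowered 7 of 28 interferon-stimulated genes (adjusted p = 2.13e-16), 7 of 22 cholesterol synthesis genes (1.4e-13), 6 of 12 fatty acid synthesis genes (8.02e-09) and 5 of 16 immediate early genes (3.76e-08). SCD, the desaturase that makes oleic acid (ENSG00000099194; chromosome 10, 100347233 to 100364826), fell 1.45-fold, from 86.5 ± 0.826 to 59.5 ± 1.62 FPKM (SD, n = 3). EGR1 fell 1.75-fold, from 15.2 ± 1.11 to 8.72 ± 0.243 FPKM. The antioxidant enzyme HMOX1, heme oxygenase (ENSG00000100292; chromosome 22, 35380361 to 35394214), rose 1.41-fold, from 17.4 ± 1.28 to 24.5 ± 0.672 FPKM. In all 213 genes changed, 98 rising and 115 falling, a balance that turned to 104 rising and 94 falling after quantile normalization. Of the 213, 1 rise and 3 falls exceeded 1 log2 unit, none of them in a protein-coding gene: the small nuclear RNA RNVU1-27 (1.08), the pseudogenes ENSG00000226396 (-1.93) and ENSG00000224114 (-1.47), and an unnamed locus on an alternate copy of the MHC region, all named after their values were seen.

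The largest rises among protein-coding genes were in GPAT3, an acyltransferase of triglyceride synthesis (0.58, SE 0.089, adjusted p = 0.014), butyrylcholinesterase BCHE (0.50, SE 0.037, adjusted p = 0.000226), the kinase LRRK2 (0.49) and the T-box factor EOMES (0.47). They were followed by HMOX1 (0.47, SE 0.056, adjusted p = 0.00345), GLT1D1 (0.45), the kinase MAP4K4 (0.43) and the quinone reductase NQO1 (0.41). After EGR1 (-0.74, SE 0.053, adjusted p = 0.000226), the largest fall among protein-coding genes was in SREBF1, the transcription factor of fatty acid synthesis (-0.57, SE 0.056, adjusted p = 0.00125). SCD (-0.53, SE 0.022, adjusted p = 3.77e-06), the calcium-binding protein S100A4 (-0.48), the GTPase RAB31 (-0.48) and CSF2RB (-0.47) fell as well. CLEC4C (-0.54) and CCL20 (-0.51) also fell, but CLEC4C lost its call without any 1 library except pH 7.4 replicate 1 (adjusted p from 0.0527 to 0.129), without a filter on low values (0.0982) and with a term for the replicate number (0.0733). CCL20 lost its call without any 1 library of pH 6.8, pH 7.4 replicate 2, NMN replicate 1 or 2, or PARP1 inhibitor replicate 2 or 3 (adjusted p from 0.0533 to 0.129). The same held without a filter (0.108), with an offset of 0.1 (0.0505) and with a term for the replicate number (0.0615).

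Interferon-stimulated genes fell in 7 of 28 measured members, and in 20 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 2.13e-16); the antiviral gene IFIT1 changed by -0.44. Cholesterol synthesis genes fell in 7 of 22 (11 adjusted over the list alone, median -0.16, adjusted p = 1.4e-13), among them INSIG1 (-0.33) and the farnesyl diphosphate synthase FDPS (-0.28). Fatty acid synthesis genes fell in 6 of 12 (7 fell and 1 rose adjusted over the list alone, median -0.25, adjusted p = 8.02e-09), with the desaturase FADS2 at -0.38. Immediate early genes fell in 5 of 16 (9 adjusted over the list alone, median -0.15, adjusted p = 3.76e-08), with the phosphatase DUSP2 at -0.45 after EGR1. Replication-dependent histones rose as a list (median 0.19, adjusted p = 0.000546), though 1 of 22 members, H1-2 (0.30), passed by itself and 6 rose adjusted over the list alone. These 5 lists kept an adjusted p under 0.05 with an estimated correlation. Over the alternatives, that correlation included, their highest adjusted p ran from 0.000445 (interferon-stimulated genes) to 0.0321 (histones).

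Another 6 lists passed with the preset correlation and moved by small medians. NF-kB targets lay at -0.07 (1 of 18 fell; 5 fell and 1 rose adjusted over the list alone, adjusted p = 0.003), with CCL22 at -0.33, and adjusted p = 0.213 with an estimated correlation. Without a filter on low values that list did not pass (adjusted p = 0.106, from 0.000861 to 0.213 over the alternatives). B cell identity genes lay at -0.07 (3 of 23 fell, 4 adjusted over the list alone, adjusted p = 0.000686), with adjusted p = 0.102 with an estimated correlation. DNA replication genes lay at 0.07 (1 of 41 rose, 8 adjusted over the list alone, adjusted p = 9.22e-05), with adjusted p = 0.206 with an estimated correlation. Fatty acid oxidation genes lay at 0.03 (2 of 17 rose, 4 adjusted over the list alone, adjusted p = 0.0353), CPT1A rising by 0.33, with adjusted p = 0.206 with an estimated correlation. The ATF4 list lay at -0.05 (adjusted p = 0.0353), with no member passing by itself, and adjusted p = 0.369 with an estimated correlation. T and NK cell markers lay at -0.07 (1 of 5 fell, also adjusted over the list alone, adjusted p = 0.0483), with adjusted p = 0.206 with an estimated correlation. The last 3 of these calls also depended on single libraries. Fatty acid oxidation was lost without pH 6.8 replicate 1 (adjusted p = 0.0991) or 2 (0.0592) or NMN replicate 3 (0.084), and ATF4 without pH 6.8 replicate 3 (0.246) or NMN replicate 1 (0.0623) or 2 (0.0621). T and NK cell markers were lost without pH 6.8 replicate 1 (0.161), NMN replicate 1 (0.0544) or 2 (0.157), or PARP1 inhibitor replicate 1 (0.0594), 2 (0.0583) or 3 (0.0891). With only the 6 libraries compared all 3 were lost (0.0631 for fatty acid oxidation and ATF4, 0.142 for T and NK cell markers). A term for the replicate number ended 2 of them, fatty acid oxidation (0.052) and T and NK cell markers (0.0541). The markers were lost with voom (0.0649) and with an offset of 0.1 (0.0665) as well.

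None of the NAD+ genes fixed beforehand passed with NMN: NAMPT was at 0.02 (adjusted p = 0.874), NMNAT1 at 0.16 (0.239), CD38 at -0.08 (0.679), SIRT1 at -0.05 (0.807) and PARP1 at 0.01 (0.874), and the NAD metabolism list had an adjusted p of 0.561. TXNIP (-0.07, adjusted p = 0.454), HK2 (-0.02, 0.854), CDKN1A (-0.12, 0.2) and MDM2 (0.08, 0.605) did not pass either. The NRF2 target list, to which HMOX1 and NQO1 belong, did not pass (adjusted p = 0.0738). It passed without a filter on low values (0.0157), and without pH 6.8 replicate 3 (0.0477) or NMN replicate 1 (0.0322) or 2 (0.0404).

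At an unadjusted p under 0.05, 1918 genes differed with NMN, and 20.81% of tested genes had groups that did not overlap, against 10% by chance. The count of 213 rests on the spread pooled over all groups, and it was 11 with only the 6 libraries compared. With those 6 the calls of EGR1, SCD, SREBF1, S100A4, BCHE and GLT1D1 held. The calls of the other protein-coding genes named above as changed with NMN were lost (adjusted p from 0.0519 to 0.129), among them HMOX1 (0.059), NQO1 (0.0519), FADS2 (0.0519), FDPS (0.0519) and CSF2RB (0.0857). H1-2 also lost its call without a filter on low values (0.0502). Without 1 library it was 46 (NMN replicate 1), 86 (NMN replicate 2), 95, 67 and 74 (pH 6.8 replicates 1, 2 and 3), 128 (pH 7.4 replicate 2) or 140 (PARP1 inhibitor replicate 1). Without NMN replicate 1 the calls of GPAT3, LRRK2, DUSP2, H1-2 and CCL22 were lost (adjusted p from 0.0511 to 0.064), as were those of H1-2 without pH 6.8 replicate 1 (0.0631), GPAT3, DUSP2 and H1-2 without replicate 2 (0.0516 to 0.0651), and GPAT3 without replicate 3 (0.0558).

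Adding the PARP1 inhibitor to the acid culture raised 31 of 33 p53 targets (adjusted p = 2.18e-21) and 13 of 18 NF-kB targets (9.6e-10). It lowered 16 of 29 MYC and ribosome biogenesis genes (2.79e-08) and 18 of 34 G2/M and mitosis genes (9.55e-08). CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases (ENSG00000124762; chromosome 6, 36676460 to 36687337), rose 1.95-fold, from 124.1 ± 6.75 to 242.3 ± 4.31 FPKM (SD, n = 3). TNFSF4, the T cell costimulator OX40 ligand (ENSG00000117586; chromosome 1, 173183731 to 173207331), rose 2.63-fold, from 15.1 ± 0.867 to 39.6 ± 0.871 FPKM. In all 2994 genes changed, 1761 rising and 1233 falling, with 37 rises and 19 falls of over 1 log2 unit.

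Other large rises were in IL12B, the shared subunit of interleukins 12 and 23 (1.43, SE 0.095, adjusted p = 6.08e-06), the stress cytokine GDF15 (1.37, SE 0.17, adjusted p = 0.00027), the keratin KRT17 (1.32) and the thrombin receptor F2R (1.31, SE 0.072, adjusted p = 2.06e-06). HLA-DPA1, also of the MHC region, had the largest fitted rise (3.10, SE 0.935, adjusted p = 0.035), but its FPKM differed over 4-fold between replicates, as did that of CHORDC1 (-1.10). The call of HLA-DPA1 was lost without pH 6.8 replicate 1 (adjusted p = 0.0892) or 2 (0.116) or PARP1 inhibitor replicate 1 (0.12) or 3 (0.0649), and that of CHORDC1 without pH 6.8 replicate 1 (0.0573) or 3 (0.0595) or PARP1 inhibitor replicate 2 (0.0513). HLA-DPA1 also lost it without a filter on low values (0.106), with an offset of 0.1 (0.0555), with a robust variance prior (0.0584) and with voom (0.15). CHORDC1 lost it without a filter (0.0639) and with only the 6 libraries compared (0.0763). Besides CHORDC1, the largest falls among protein-coding genes were in VPREB3, a chaperone of the pre-B cell receptor (-1.10, SE 0.249, adjusted p = 0.00947), and the MYC target CDCA7 (-0.96, SE 0.072, adjusted p = 1.24e-05). HPDL (-0.92), the serine protease PRSS21 (-0.89), the histone H2BC11 (-0.87), the ubiquitin hydrolase UCHL1 (-0.85) and LAMP5 (-0.84) followed.

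Of 33 measured p53 targets, 31 rose and all 33 rose adjusted over the list alone, with a median of 0.50 (camera adjusted p = 2.18e-21). GADD45A rose by 0.96, TRIM22 by 0.50, and BTG2 and MDM2 by 0.43 each. NF-kB targets rose in 13 of 18 (16 adjusted over the list alone, median 0.30, adjusted p = 9.6e-10), with CCL22 at 0.75, CFLAR at 0.54, TNFAIP3 at 0.44 and CD83 at 0.42. Apoptosis genes rose in 12 of 25 (15 adjusted over the list alone, median 0.22, adjusted p = 3.98e-06); they included the protective BCL2L1 (0.62) and BIRC2 (0.41) and the death-promoting PMAIP1 (0.44) and TNFRSF10B (0.34). MYC and ribosome biogenesis genes fell in 16 of 29, also 16 adjusted over the list alone (median -0.13, adjusted p = 2.79e-08), MYC itself falling by 0.27. G2/M and mitosis genes fell in 18 of 34 (20 adjusted over the list alone, median -0.12, adjusted p = 9.55e-08), with CDC20 at -0.24, BUB1 at -0.21 and PLK1 at -0.20. These 5 lists kept an adjusted p under 0.05 with an estimated correlation, most of them narrowly. Over the alternatives, that correlation included, the highest adjusted p was 0.000142 for p53 targets and 0.0429 for NF-kB targets. It was 0.0427 for MYC and ribosome biogenesis, 0.0446 for apoptosis and 0.0446 for G2/M.

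The other 9 lists that passed did so only with the preset correlation. Cholesterol synthesis genes rose in 11 of 22, the count also adjusted over the list alone (median 0.13, adjusted p = 0.000759), with STARD4 at 0.41 and SC5D at 0.28, and adjusted p = 0.088 with an estimated correlation. The vacuolar ATPase, the proton pump of lysosomes, rose in 10 of 16 (11 rose and 1 fell adjusted over the list alone, median 0.19, adjusted p = 0.00221), with ATP6AP2 at 0.28 and ATP6V1A at 0.23, and adjusted p = 0.088 with an estimated correlation. Lysosomal genes rose in 11 of 27 (13 adjusted over the list alone, adjusted p = 0.00856), led by the protease CTSH (0.40), with adjusted p = 0.245 with an estimated correlation. Hypoxia-inducible factor targets rose in 6 of 15 and fell in 1, the same counts adjusted over the list alone (adjusted p = 0.0369), BHLHE40 rising by 0.61, with adjusted p = 0.134 with an estimated correlation. Genes of the mitochondrial genome rose in 10 of 13 (11 adjusted over the list alone, median 0.19, adjusted p = 0.00027, and adjusted p = 0.373 with an estimated correlation). All genes of the mitochondrial chromosome together took 8.30 ± 0.052% of reads against 7.35 ± 0.114% (SD, n = 3). After quantile normalization the median of the 13 was 0.00 (adjusted p = 0.938, from 1.38e-05 to 0.938 over the alternatives). Histone genes fell in 6 of 22 and rose in 1, also adjusted over the list alone (median -0.12, adjusted p = 0.0135), with H2BC12 at -0.83, and adjusted p = 0.102 with an estimated correlation. Without a filter on low values that list did not pass (adjusted p = 0.376, from 0.00868 to 0.376 over the alternatives). DNA replication genes fell in 13 of 41 and rose in 3 (14 and 3 adjusted over the list alone, adjusted p = 0.000982), TYMS rising by 0.42, with adjusted p = 0.245 with an estimated correlation. Cytosolic ribosomal proteins fell in 10 of 69 and rose in 1, also adjusted over the list alone (median -0.05, adjusted p = 0.00525), with adjusted p = 0.764 with an estimated correlation. Homologous recombination and Fanconi anaemia genes, which repair the breaks left when PARP1 is blocked, fell in 3 of 33, which did not pass adjusted over the list alone (median -0.07, adjusted p = 0.0114), with adjusted p = 0.21 with an estimated correlation.

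Of the NAD+ genes fixed beforehand, NAMPT rose by 0.23 (adjusted p = 0.000743) and NMNAT1 by 0.24 (adjusted p = 0.017), while PARP1 (-0.05, adjusted p = 0.334, and 0.0384 after quantile normalization), SIRT1 (-0.05, 0.62) and CD38 (0.14, 0.206) did not pass. HK2 fell by 0.10 (adjusted p = 0.0254), TXNIP was at -0.09 (0.138, and 0.0219 without PARP1 inhibitor replicate 2), and the NAD metabolism list did not pass (0.135, and 0.05 after rounding without a filter on low values, where it passed). At an unadjusted p under 0.05, 4384 genes differed, and 42.29% of tested genes had groups that did not overlap, against 10% by chance. The call of NMNAT1 was lost without pH 6.8 replicate 3 (adjusted p = 0.0612) or PARP1 inhibitor replicate 1 (0.0588) or 2 (0.0577), and that of HK2 without pH 6.8 replicate 1 (0.0526) or 2 (0.095) or PARP1 inhibitor replicate 1 (0.0956) or 2 (0.0684). HK2 also lost it without a filter on low values (0.0504) and with only the 6 libraries compared (0.0825). Hypoxia-inducible factor targets lost theirs without pH 6.8 replicate 3 (0.0536), NMN replicate 3 (0.0507) or PARP1 inhibitor replicate 2 (0.0636), and with only the 6 libraries compared (0.0675).

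**Figure D2:**
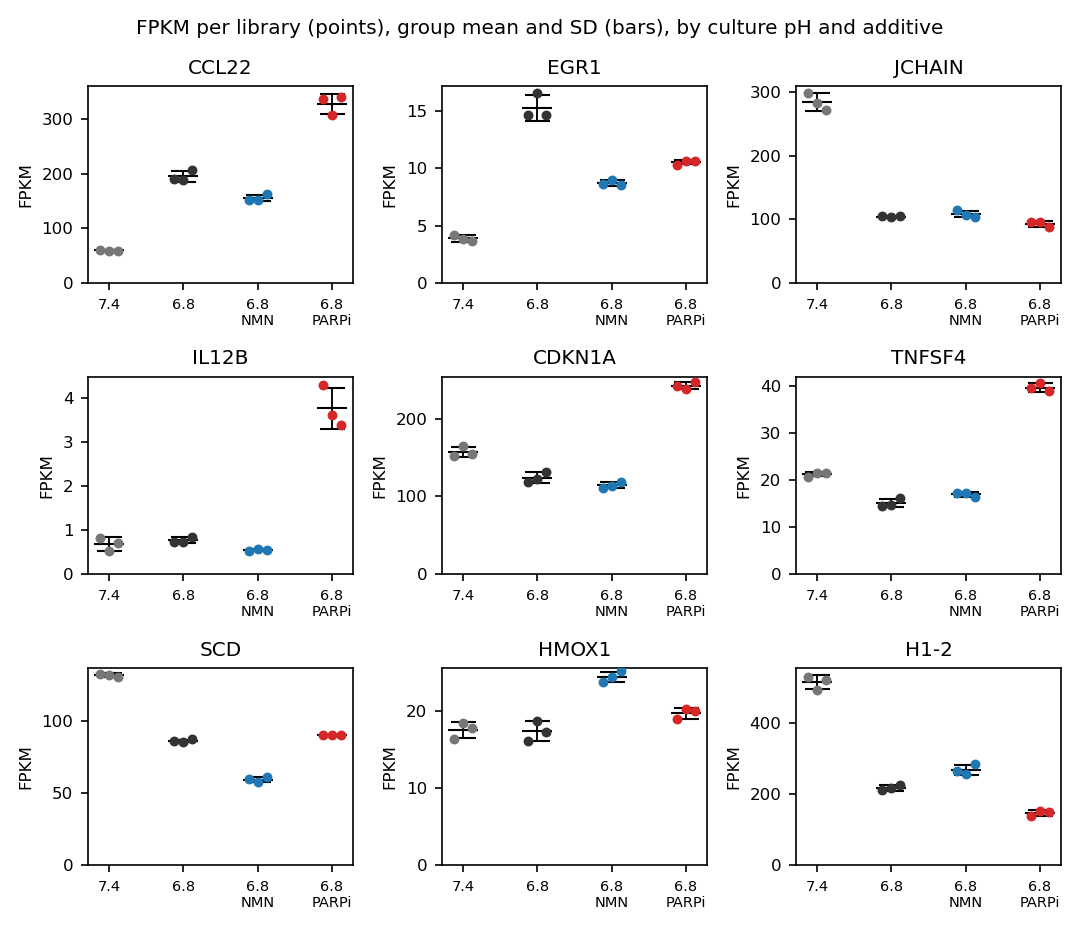
FPKM (y axis) of 9 genes in each library (points), with the group mean and SD (bars, n = 3), by culture pH and additive (x axis; PARPi, PARP1 inhibitor). CDKN1A stood at 157.1 FPKM at pH 7.4, 124.1 at pH 6.8 and 242.3 with the PARP1 inhibitor, while the means of JCHAIN lay between 93.0 and 108.5 in the 3 groups at pH 6.8.

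Tested directly against each other at pH 6.8, NMN and PARP1 inhibitor cultures differed in 2592 genes, of which 1015 were higher and 1577 lower with NMN. CDKN1A was 2.12-fold lower with NMN (114.2 ± 3.69 against 242.3 ± 4.31 FPKM; SD, n = 3) and TNFSF4 2.34-fold lower (16.9 ± 0.552 against 39.6 ± 0.871 FPKM). IL12B (-1.62, SE 0.095, adjusted p = 3.3e-06), GDF15 (-1.28), KRT17 (-1.23), the adhesion protein NECTIN4 (-1.18) and the p53-binding ZNF385A (-1.17) were lower with NMN as well, as was LCE1C (-1.40). Histone genes H2BC11 (1.13, SE 0.07, adjusted p = 4.43e-06), H2BC17 (1.09), H2BC12 (1.04), H1-2 (0.86) and H2AC18 (0.79) led the genes higher with NMN, beside OR2B6 (0.96) and PLAAT2 (0.78). With only the 6 libraries compared H2AC18 lost its call (adjusted p = 0.0506). CHORDC1 (0.96) differed over 4-fold between replicates, and its call was lost without any 1 library except pH 7.4 replicate 3 and PARP1 inhibitor replicate 3 (adjusted p from 0.0514 to 0.106). That call was also lost without a filter (0.126), with only the 6 libraries compared (0.127), an offset of 0.1 (0.0592), a term for the replicate number (0.064) or a robust variance prior (0.0528).

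With NMN, 32 of 33 p53 targets were lower than with the inhibitor, and 33 adjusted over the list alone (median -0.48, adjusted p = 3.68e-22). NF-kB targets (15 of 18 lower, 16 adjusted over the list alone, median -0.35) and cholesterol synthesis genes (18 of 22, 19 adjusted over the list alone, -0.33, FDPS at -0.47) were lower. So were interferon-stimulated genes (20 of 28, 22 adjusted over the list alone, -0.21, OAS3 at -0.38) and apoptosis genes (12 of 25, also adjusted over the list alone, -0.12, BCL2L1 at -0.64). Histones (7 of 22 higher, also adjusted over the list alone, 0.34) and MYC and ribosome biogenesis genes (18 of 29, 22 adjusted over the list alone, 0.15) were higher. So were G2/M genes (17 of 34, 22 adjusted over the list alone, 0.15) and DNA replication genes (20 of 41 higher and 1 lower, 26 and 1 adjusted over the list alone, 0.15, MCM4 at 0.31). These 9 lists had adjusted p from 3.68e-22 to 1.57e-05, and all kept their calls with an estimated correlation, DNA replication at adjusted p = 0.0459 with an estimated correlation.

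In this direct test 10 lists passed with the preset correlation alone. Lower with NMN were genes of the mitochondrial genome (11 of 13; median -0.23, adjusted p = 1.63e-06, and adjusted p = 0.169 with an estimated correlation), whose median turned to 0.02 after quantile normalization (adjusted p = 0.995, from 1.87e-08 to 0.995 over the alternatives). Immediate early genes (9 of 16 lower and 2 higher, JUNB at -0.52) had adjusted p = 0.0623 with an estimated correlation, and B cell identity genes (9 of 23, SPIB at -0.50) adjusted p = 0.12 with an estimated correlation. MHC class II (3 of 8) and fatty acid synthesis (6 of 12) genes each had adjusted p = 0.169 with an estimated correlation. The vacuolar ATPase (6 of 16) had adjusted p = 0.0728 with an estimated correlation, and hypoxia-inducible factor targets (7 of 15) adjusted p = 0.0775 with an estimated correlation. Higher with NMN were homologous recombination genes (8 of 33, RAD54L at 0.24), with adjusted p = 0.075 with an estimated correlation, and heat shock genes (4 of 14), with adjusted p = 0.194 with an estimated correlation. NRF2 targets (6 of 22 higher and 1 lower), led by NQO1 (0.45), the ferritin chain FTL (0.44), TXNRD1 (0.35) and GCLC (0.34), had adjusted p = 0.206 with an estimated correlation. These 10 lists had adjusted p from 1.63e-06 to 0.0397 with the preset correlation. Heat shock genes lost that call without pH 6.8 replicate 1 (0.0537), NMN replicate 2 (0.0528) or PARP1 inhibitor replicate 3 (0.0541), and without NMN replicate 3 so did hypoxia-inducible factor targets (0.0575) and NRF2 targets (0.0543). At a mean of at least 5 FPKM NRF2 targets (0.0558) and heat shock genes (0.0939) were lost. Heat shock genes were also lost with only the 6 libraries compared (0.0584), a term for the replicate number (0.0574), no variance trend (0.0598) or no unstable genes (0.0731).

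NAMPT was lower with NMN than with the inhibitor (-0.21, adjusted p = 0.0013), as was MDM2 (-0.35, adjusted p = 0.0049), while CD38 (-0.22, 0.066), HK2 (0.09, 0.0544), PARP1 (0.06, 0.218), NMNAT1 (-0.08, 0.391), TXNIP (0.02, 0.763) and SIRT1 (0.01, 0.948) did not pass. CD38 passed without pH 7.4 replicate 2 (adjusted p = 0.0388) or 3 (0.0386) and with voom (0.0462). HK2 passed without PARP1 inhibitor replicate 3 (0.0303), at a mean of at least 5 FPKM (0.0452), and after median-of-ratios scaling (0.0471) or quantile normalization (0.0172). PARP1 passed after quantile normalization (0.0179). At an unadjusted p under 0.05, 4036 genes differed, and 37.1% of tested genes had groups that did not overlap, against 10% by chance. Quantile normalization moved the share of changed genes that were higher with NMN from 39.2% to 51.2% (1398 higher and 1332 lower).

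Of the 3737 genes changed in acid culture, 2575 (68.9%) were called the same way against pH 7.4 in NMN cultures, 1157 did not pass, and 5 were changed the other way: BCHE (0.35 against pH 7.4), IFIT1 (-0.23), RAB31 (-0.24), GSDME (-0.09) and a pseudogene, ENSG00000224114 (-0.51). The call of GSDME was lost without NMN replicate 1 (adjusted p = 0.051) or pH 7.4 replicate 2 (0.0523) or 3 (0.073) and with only the 6 libraries compared (0.0847), and that of RAB31 without pH 7.4 replicate 2 (0.0544). With the PARP1 inhibitor 2421 (64.8%) were called the same way, 141 the other way, and 1175 did not pass. These comparisons share the pH 7.4 libraries, so part of the agreement may come from them. Independent lists would share 326.6 rises and 202.2 falls with NMN (1463 and 1112 observed), and 454.3 and 284.2 with the inhibitor (1434 and 987). Of the genes called in acid culture 97.6% kept their sign with NMN and 88.2% with the inhibitor. Where simulated additive cultures were back at pH 7.4 the share was 58.1% (100 draws, at most 59.7% and 60.4%). These draws called 4647 acid changes on average, against 3737 here. Only a full return to pH 7.4 was drawn, so they do not address a partial return. JCHAIN lay at -1.38 against pH 7.4 with NMN (adjusted p = 8.17e-08) and at -1.61 with the inhibitor (adjusted p = 8.47e-09), and XBP1 at -0.74 and -0.86. PRDM1 lay at -1.09 with NMN but at -0.49 with the inhibitor, which raised it by 0.72 from pH 6.8 (limma adjusted p = 1.93e-05). CCL22 stood 1.37 above pH 7.4 with NMN and 2.44 above it with the inhibitor (adjusted p = 1.23e-07 and 7.43e-10). SCD stood at -1.14 with NMN and -0.54 with the inhibitor, and CDKN1A at -0.46 with NMN and 0.62 with the inhibitor. In all 3337 genes differed from pH 7.4 with NMN (1915 higher and 1422 lower; 4663 at an unadjusted p under 0.05; 41.39% without overlap, against 10% by chance) and 4663 with the inhibitor (2664 and 1999; 5722; 51.34%). The balance with the inhibitor turned to 2362 higher and 2467 lower after quantile normalization.

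Against pH 7.4, 17 lists passed with NMN, 11 of them with an estimated correlation. The plasma cell list (17 of 20 lower, 18 adjusted over the list alone, median -0.61, adjusted p = 4.06e-16) and cholesterol synthesis (18 of 22 lower, 19 adjusted over the list alone, -0.34, adjusted p = 4.88e-14) were lowest by p. With the inhibitor 24 lists passed, 9 of them with an estimated correlation. NF-kB targets were higher (16 of 18, 17 adjusted over the list alone, median 0.65, adjusted p = 3.64e-14). Histones were lower (16 of 22, 19 adjusted over the list alone, -0.87, adjusted p = 4.41e-09), and p53 targets were higher (23 of 33 higher and 1 lower, 24 and 1 adjusted over the list alone, 0.27, adjusted p = 1.52e-07).

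Of the 115 falls with NMN, 76 were rises in acid culture, among them EGR1, CCL22 and CSF2RB, and of the 98 rises with NMN, 44 were falls in acid culture, among them H1-2. Independent lists of these sizes would share 19.6 and 13.9. Another 20 falls with NMN, such as SCD, were falls in acid culture (16.3), and 13 rises were rises (16.7). Both comparisons use the pH 6.8 libraries, which pushes them apart with no effect at all, so part of the opposed counts may come from them. Simulated unchanged groups, which leave out the effects and so have almost no calls to share (mean 0), gave a covariance of -0.02285 (95% range -0.02774 to -0.01817), against -0.03562 observed, a difference of -0.01278 (r = -0.466 over genes, which are not independent; simulated r = -0.498). With the PARP1 inhibitor the changes went both ways, and these comparisons share the pH 6.8 libraries as well. Of the acid falls 498, such as CDKN1A, rose with it (250.4 for independent lists), and of the acid rises 394, such as EGR1, fell (210.3). Another 432 acid rises, such as CCL22, rose further (300.3), and 138 acid falls, such as H1-2, fell further (175.3). Its covariance with the acid change was -0.02828 (simulated -0.02274, -0.02748 to -0.01823), a difference of -0.00554. That covariance lay inside the simulated range without pH 6.8 replicate 1 (-0.03983) or 3 (-0.03671), pH 7.4 replicate 1 (-0.028) or PARP1 inhibitor replicate 2 (-0.02743), without a filter on low values (-0.01537), and with a mean of at least 5 FPKM (-0.01808). With an offset of 0.1 the 2 covariances were -0.08541 with NMN and -0.07281 with the inhibitor, and without unstable genes -0.02112 and -0.0164, all outside their simulated ranges. The additives shared 73 rises (independent 14.4), such as BCHE and LRRK2, and 63 falls (11.9), such as EGR1. Both of these comparisons use the pH 6.8 libraries, which pushes them the same way with no effect at all. Part of the shared counts may therefore come from those libraries. The covariance between the additives was 0.03523 (simulated 0.02289, 0.01812 to 0.02793), a difference of 0.01235. It was 0.0853 with an offset of 0.1, 0.01778 without a filter and 0.02183 without unstable genes, and the acid and NMN value was -0.01823 without a filter, each outside its simulated range. Simulations drew genes independently, so the simulated ranges are too narrow if genes vary together.

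**Figure D3:**
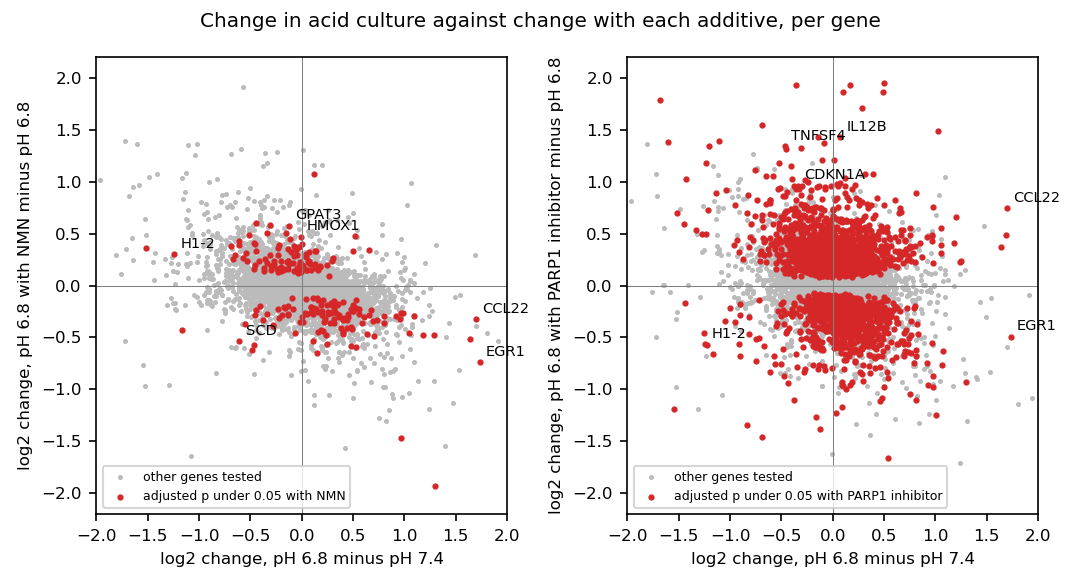
Log2 change in acid culture (x axis) against the log2 change with NMN (left y axis) or the PARP1 inhibitor (right y axis). Each of 11670 genes is a point, and genes passing the test for that additive are in red. Genes unstable between replicates and genes on chromosome Y are left out, and 6 and 5 genes lie outside the axes. Both axes use the pH 6.8 libraries, which tilts the cloud downward with no effect. EGR1 and CCL22 rose in acid culture and fell with NMN, and CDKN1A fell in acid culture and rose with the inhibitor.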

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

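Voom on recovered reads, the robust variance prior and leaving out unstable genes were chosen after the data were seen. With an estimated correlation the lists called went from 20 to 9 in acid culture and 11 to 5 with NMN. They went from 14 to 5 with the PARP1 inhibitor and 19 to 9 between the additives, for causes that were not tested. The 213 genes changed with NMN became 106 without a filter on low values, 11 with only the 6 libraries compared, which leaves fewer libraries to estimate the spread, and 140 with a term for the replicate number (of which 128 were shared with the 213). NMN replicate 3 differed most from its group. The median chi-square per gene of its read counts was 1.349 and 1.303 against the other NMN libraries, and 0.811 to 1.028 in all other replicate pairs. A spread pooled over groups may thus be too small for NMN. Leaving that library out gave 3960 genes in acid culture, 3211 with the inhibitor and 183 with NMN. Apart from the fewer libraries, the cause was not tested. The replicate numbers did not pair the libraries (correlations from -0.086 to 0.084). The mitochondrial genome list between the additives lost its call under quantile normalization, its median going from -0.225 to 0.015 (adjusted p = 0.995, from 1.87e-08 to 0.995 over the alternatives). The cause was not tested. The covariance of the acid and PARP1 inhibitor changes was -0.01537 without a filter and -0.01808 at a mean of at least 5 FPKM, inside simulated ranges of -0.01555 to -0.0123 and -0.02356 to -0.009691; the cause was not tested. Over the other settings, the genes changed ranged from 2692 to 3855 in acid culture, 2233 to 3125 with the PARP1 inhibitor, 1740 to 2741 between the additives, and 2431 to 3497 and 3366 to 4829 for NMN and the inhibitor against pH 7.4, all within 1.5 times the main counts; voom gave 303 with NMN. With each library left out they ranged from 2953 to 3960, 2314 to 3211, 1868 to 2475, 2636 to 3254 and 4028 to 4889, and with NMN from 46 to 183 (231 without unstable genes). Lists called then ranged from 19 to 21 in acid culture, 10 to 14 with NMN, 13 to 14 with the inhibitor and 18 to 21 between the additives. With each library left out, covariances ranged from -0.04861 to -0.03474 for acid and NMN, -0.04197 to -0.02743 for acid and the inhibitor, and 0.03368 to 0.04805 between the additives. Over the other settings they ranged from -0.08541 (offset 0.1) to -0.01823 (no filter), from -0.07281 to -0.01537 and from 0.01778 to 0.0853, with the same settings at the ends. Without unstable genes they were -0.02112, -0.0164 and 0.02183. The cause was not tested. For single lists, leaving out a library left the call as it was in 2062 fits, ended it in 24 and added it in 26; other settings left it in 1865, ended it in 20, added it in 38, of which 21 were without a filter on low values, and in 1 ended it with the median past 0. Of the genes followed, a left-out library ended the call of 4 of 99 in acid culture, 21 of 59 with NMN, 8 of 79 with the inhibitor and 1 of 54 between the additives. Other settings ended the call of 5 of 99, 35 of 59, 6 of 79 and 2 of 54, and all 35 with NMN were lost with only the 6 libraries compared. These totals count every gene followed, including genes with no call to lose, such as NAMPT, CDKN1A and MDM2 with NMN. The shares of calls lost were therefore higher than these counts give. No call was replaced by one in the other direction. Some alternative added a call for 1 of the 99, 2 of the 59, 3 of the 79 and 3 of the 54. After quantile normalization the rises and falls were 1907 and 1905 in acid culture, 104 and 94 with NMN, 1557 and 1462 with the inhibitor, and 2362 and 2467 for the inhibitor against pH 7.4; the cause was not tested. Where a left-out library leaves a group with 2, that group is assumed to vary like the others.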

Other observations

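The tests of the MHC region, of S phase, of near-0 genes without an overlapping gene, and of covariances with no shared library were chosen only after the results were seen, as were the groups of immunoglobulin genes, long noncoding RNAs and crossed genes.

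Some genes that nearly every cell expresses were listed near 0 in all groups: COX5B, MRPS12, NDUFB10, NDUFA6 and NDUFS3 had 0 reads, RPS18 a mean of 0.0683 FPKM, SDHB 0.0815 and LDHA 0.0511. Overlap with another gene on the same strand was not clearly more frequent among the 19 near-0 members of ubiquitous lists (9, or 47.4%) than among the others (80 of 205, or 39.0%), by Fisher's exact test (two-sided p = 0.475). Of the 19, 10 had no such overlap, which argues against overlap with a named gene as the cause for those. Unnamed loci were left out of this count, so overlap with one of them stays possible. Among antigen presentation genes, 14 of 21 inside the MHC region (chromosome 6, 28 to 34 Mb) were under 1 FPKM against 0 of 10 outside it (Fisher's exact test, two-sided p = 0.000461), so reads shared with alternate copies of that region may explain HLA-DRA (0.0785) and TAP1 (0.0125). What removed the reads of COX5B and LDHA, which lie elsewhere, stays open, and no biological explanation was tested. Values near 0 of such genes do not show that they are silent.

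Histone mRNAs, which lack a poly(A) tail, fell at pH 6.8 with a median of -0.766. For fewer cells in S phase, a bound of -0.383 was set for DNA replication genes, from the histone median and after the results were seen. Their median was -0.085 (95% bootstrap interval over genes -0.108 to -0.007), so they fell less than that. How far they fall with fewer cells in S phase was not measured, so this test cannot decide. Another 7 RNAs without a tail had a median of -0.406. That met their own bound, also -0.383, whose rule was written beforehand. The interval of -1.401 to 0.03 spans that bound, with SCARNA9 rising (1.02) and RN7SL3 falling (-1.65). Lower capture of RNAs without a tail and a change in histone mRNA itself therefore cannot be told apart with so few RNAs. The first would also require that RNA was selected by its tail, and how RNA was selected is not stated here. Fewer cells in S phase stays open as well.

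NMN changes opposed acid changes, with a covariance of -0.03562. The shared pH 6.8 libraries alone gave -0.02774 to -0.01817 in simulations, so they do not account for all of it, although the simulations drew genes independently. With no pH 6.8 library shared between the changes, 6 ways of dividing them gave a mean of -0.01317 (-0.01828 to -0.009757), and -0.01015 without unstable genes. The same division gave -0.005828 (-0.01153 to -0.002691) for acid and the PARP1 inhibitor and 0.01278 (0.009424 to 0.01602) between the additives. Partial opposition of the acid state by NMN is a hypothesis that these values leave open, since culture differences between groups may act the same way.

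The 6 libraries of each comparison can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the only 1 of 10 with as many genes in each comparison: 3737 genes in acid culture, 213 with NMN, 2994 with the PARP1 inhibitor, 2592 between the additives, and 3337 and 4663 for NMN and the inhibitor against pH 7.4, against a highest other value of 1 each. Splits that mix the groups add any difference between them to the spread. Their low counts therefore do not tell what made the groups differ.

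Of 13 tested immunoglobulin constant and variable genes, 9 fell in acid culture (median -1.09), 1 fell with NMN, and 6 fell and 1 rose with the PARP1 inhibitor; reads can be shared among such paralogs. IGLV6-57 went from 1808 ± 27.9 FPKM at pH 7.4 to 749.7 ± 55.7 at pH 6.8 and 1057 ± 78.2 with the inhibitor (SD, n = 3). Of 1067 tested long noncoding RNAs, 87 rose and 109 fell in acid culture, 3 rose and 10 fell with NMN, and 79 rose and 119 fell with the inhibitor. LINC02051 rose from 3.88 ± 1.08 to 14.7 ± 0.0288 FPKM with the inhibitor (SD, n = 3). Among the 141 genes that acid culture moved 1 way and the inhibitor took past pH 7.4, 102 fell first, such as TNFSF4, F2R and SULF2, and 39 rose first, such as UCHL1 and PRSS21. Of markers of other cell types, 5 of 17 for T and NK cells reached 1 FPKM (TRAC highest, 92.7), against 2 of 14 monocyte and macrophage markers (ITGAM, 3.72), 3 of 13 fibroblast and epithelial markers (CDH1, 3.41), and 0 of 10 erythroid markers (ALAS2, 0.0951).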
